A study of Homo sapiens with 9 samples.

How the data were processed

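Polyadenylated RNA was sequenced from PANC-1 cells, an established human pancreatic carcinoma line, in 9 libraries that the sample titles divide into 3 groups of 3: NC, ACSS2-KO-2 and ACSS2-KO-3. Per the labels' protocols, messenger RNA was selected with oligo(dT) beads, fragmented, copied with a dUTP-marked second strand and sequenced from both ends. Per the submitters' processing notes, the build was GRCh38 and the tools included cutadapt 1.9, HISAT2 2.2.1 and StringTie 2.1.6, with DESeq2 and edgeR named without versions. Which of these made the counts, the counting settings and the strand setting are not given in the sources used here. The treatment labels of the 6 knockout samples run from ACSS2-KO to ACSS7-KO with the sample number, whereas their titles give ACSS2-KO-2 and ACSS2-KO-3, so the titles were used. What the 2 and the 3 of the titles stand for (a guide, a clone or a pool) and what NC stands for are not stated.

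The deposited table, made by the authors, holds whole-number counts per gene with 1 column per library and no scaling between libraries. It lists 58735 genes, of which 25850 had a count of 0 in every library. All identifiers, with their start and end positions, matched GENCODE release 29. Library totals were 15474995, 14906798 and 16326713 counts in NC, 16813763, 14756572 and 15911310 in ACSS2-KO-2, and 16305021, 17457190 and 16144829 in ACSS2-KO-3. A count of 0 in 1 library allows up to 3 counts, which is a normalised count (counts per 1000000, CPM) of 0.172 to 0.206 depending on the library. A fold against a group at 0 in every library, or with a mean under its floor, was computed as a lower bound, with the mean of that group's per-library floors in place of its level. For genes with 1 to 3 counts in a group, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only.

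Counts were scaled with TMM factors in edgeR 4.0.16 (R 4.3.3) and filtered by group with filterByExpr, with a minimum count of 10 and a minimum total of 15, which left 15811 genes. Levels are CPM with these factors, as mean and SD over the 3 libraries of a group. One quasi-likelihood model of the 9 libraries, with 1 mean per group and 6 residual degrees of freedom, was fitted with glmQLFit and tested with glmQLFTest. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as a change. The tests were 2-sided. The common dispersion was 0.00291, a low value for separate cultures. The sources do not say that the libraries of a group came from separate cultures, and if they did not, the p-values measure only the spread between these libraries, which may be technical.

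4 comparisons were made: ACSS2-KO-2 against NC, ACSS2-KO-3 against NC, the mean of both knockout groups against NC, and ACSS2-KO-3 against ACSS2-KO-2. The replicate numbers of the titles were checked for pairing. The correlations of residuals between libraries of the same number in different groups ran from -0.041 to 0.056 and 0 of 9 exceeded 0.1, so the numbers were not used as pairs. The labels give no batch. Because both knockouts were set against the same 3 NC libraries, the correlation and covariance of their fold changes were compared with 20 simulations of unchanged groups that shared their controls. The 3 NC libraries cannot be divided into 2 sets of at least 2.

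24 gene lists with 606 genes were fixed, of which 523 genes were tested and 9 were found through their current symbols. The lists were BCAA catabolism (branched-chain amino acids), amino acid transporters, acetyl-CoA supply, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation, ATF4 stress response, ER chaperones, polyamine metabolism, lysosome and autophagy, cell cycle, p53 targets, hypoxia targets, glycolysis, interferon response, NF-kB and cytokines, epithelial markers, mesenchymal and matrix genes, MAPK feedback genes, immediate early and heat shock genes, acinar and islet markers, immune and endothelial markers, mitochondrial genome transcripts, and cytosolic ribosomal proteins. Each list was tested with camera (limma 3.58.1), which compares its genes with all others, with a preset correlation of 0.01 between genes and again with the correlation estimated from the residuals. The fry test asked whether the genes of a list moved one way on balance, without comparing them with other genes. List p-values were adjusted over the 24 lists. Members are counted as risen or fallen after adjustment over all tested genes and, separately, adjusted over the list alone. Where a list's median took in members at 0 in a group, placing them at their bound shifted no median.

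Named genes followed a rule. It took ACSS2, BCAT1, BCAT2, ETV4, SLC39A4 and SAT1 in every case. It took the 10 genes that rose and the 10 that fell in both knockouts with the largest smaller fold, provided that all 6 knockout libraries lay on one side of NC and the higher group averaged at least 1 CPM. It took up to 2 members per list with the smallest p in the mean comparison. For ACSS2-KO-3 against ACSS2-KO-2 it took the 5 highest and 5 lowest folds without overlap of libraries and with at least 1 CPM. Genes with no symbol, and X-inactivation or Y-linked genes, were not named. The groups, comparisons, tests, lists, naming rule and most alternative settings were set before the data were examined.

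A trend of fold change with GC content was found in the data. A further fit, chosen after seeing the data, entered per-library robust spline trends of GC content and transcript length (5 degrees of freedom) as offsets. GC content and length were taken from the GENCODE 29 transcripts and were available for 99.96% of the tested genes. Values from this fit are called values with the offsets. Such offsets remove the trend whatever its origin.

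The pipeline was tested on simulated data built from these libraries, with 50 changed genes per fold. For ACSS2-KO-2 against NC the model recovered 74% of 1.5-fold, 84% of 2-fold, 94% of 4-fold and 92% of 8-fold changes with 10 false calls (5.49%). For ACSS2-KO-3 against NC it recovered 72%, 78%, 92% and 92% of the same folds with 11 false calls (6.18%). A simulated GC trend in the ACSS2-KO-3 libraries produced 5798 false calls without the offsets and 14 with them. That trend was built on the same GC values that the offsets use. Its removal therefore does not show how well the offsets remove a trend from the real libraries. A list shifted 1.5-fold in both knockouts gave a camera adjusted p of 4.78e-62, or adjusted p = 0.000815 with an estimated correlation, and 0 of the 23 other lists passed either test. Genes were simulated independently of each other. The simulation therefore does not show how either list test behaves where the genes of a list are correlated.

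The alternatives tried were RLE and upper quartile scaling, DESeq2 1.42.0, limma-voom, no low-count filter, a mean of at least 1 CPM, a fold of at least 2, only the libraries of the groups compared, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were the offsets, a restriction to genes at 1 CPM or more in NC, and a model of 2 groups with the 6 knockout libraries as 1 group. Alternatives for FPKM values were not run because the table holds counts only. Reads, transcript isoforms and protein data were not used here.

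Counts of genes with near-identical copies are uncertain, because how reads with several positions were counted is not stated. Among named genes this applies to RN7SL5P, RNU6-1, FTH1P11, HSPA1B, the ribosomal protein genes and the mitochondrial genes. CDKN2A overlaps CDKN2B-AS1 on the other strand, and with the strand setting unstated their counts may not be fully separate.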

Results

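RNA levels were measured in 9 libraries of PANC-1 cells, an established human pancreatic carcinoma line, in 3 groups of 3: NC, ACSS2-KO-2 and ACSS2-KO-3. ACSS2 is the cytosolic and nuclear enzyme that makes acetyl-CoA from acetate, and the series title links it to BCAT1 and branched-chain amino acid (BCAA) metabolism. The comparisons ask how the transcriptome of each knockout differed from NC and whether both knockouts moved alike. Totals ran from 14756572 to 17457190 counts per library, and the median tested gene had 305 counts. Between 24476 and 24496 genes had at least 1 count in the NC libraries, 24572 to 25185 in ACSS2-KO-2 and 22311 to 23183 in ACSS2-KO-3. Correlations of log levels across genes were 0.991 to 0.993 within a group, 0.979 to 0.982 between NC and ACSS2-KO-2, and 0.961 to 0.972 between NC and ACSS2-KO-3. Genes are not independent replicates in such correlations. The first principal component, with 60.6% of the variance, set ACSS2-KO-3 apart from the other libraries, and the second, with 18.1%, separated NC from ACSS2-KO-2.

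ACSS2 (ENSG00000131069, chromosome 20, 34872146 to 34927962) was lower in each of the 6 knockout libraries than in any NC library. Its level was 33.3, 30.6 and 28.3 CPM in the NC libraries, 15.1, 14.7 and 12.4 CPM in ACSS2-KO-2, and 7.19, 8.57 and 8.50 CPM in ACSS2-KO-3. The group values were 30.7 ± 2.53, 14.1 ± 1.45 and 8.09 ± 0.779 CPM (SD, n = 3 each). ACSS2 RNA remained at 45.8% of NC in ACSS2-KO-2 (95% interval 39.8 to 52.6%) and at 26.4% in ACSS2-KO-3 (22.6 to 30.7%), with edgeR adjusted p values of 5.26e-09 and 1.49e-14. It was lower in ACSS2-KO-3 than in ACSS2-KO-2 by a log2 difference of -0.80 (edgeR adjusted p 1.05e-06). RNA levels alone do not show how much functional protein a knockout keeps.

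BCAT1 (ENSG00000060982, chromosome 12, 24810022 to 24949459), the cytosolic aminotransferase that starts the breakdown of branched-chain amino acids, fell in both knockouts. It measured 20.5, 20.1 and 17.5 CPM in NC, 7.38, 11.2 and 9.70 CPM in ACSS2-KO-2, and 1.37, 1.64 and 1.78 CPM in ACSS2-KO-3. The log2 fold changes were -1.04 (SE 0.127, edgeR adjusted p 1.62e-06) and -3.59 (SE 0.171, 6.86e-16), or 48.7% and 8.3% of NC, and with the offsets for GC content and length the ACSS2-KO-3 value was -2.74. The series title names BCAT1, so its fall is not independent evidence. BCAT2 (ENSG00000105552), its mitochondrial counterpart, measured 43.7 ± 2 CPM in NC, 44.1 ± 2.97 in ACSS2-KO-2 and 48.5 ± 3.61 in ACSS2-KO-3 and did not pass the test (edgeR adjusted p 0.94 and 0.0741). For BCAT2 in ACSS2-KO-3 the log2 fold change of 0.15 passed with RLE scaling (0.16, adjusted p 0.0478), without NC replicate 1 (0.19, 0.0444) and without ACSS2-KO-3 replicate 2 (0.22, 0.0133), and was -0.07 with the offsets. SAT1 (ENSG00000130066), which acetylates spermidine and spermine with acetyl-CoA, fell from 436 ± 23 CPM in NC to 326 ± 18.3 in ACSS2-KO-2 and 177 ± 1.89 in ACSS2-KO-3 (log2 fold change -0.42, edgeR adjusted p 2.4e-06, and -1.30, 4.07e-17). ETV4 (ENSG00000175832), a transcription factor of the ETS family, was 0.24 above NC in ACSS2-KO-2 (edgeR adjusted p 0.132) and rose by 0.52 in ACSS2-KO-3 (2.25e-05). With the offsets the ETV4 values were 0.26 (edgeR adjusted p 0.0701) and 0.29 (0.00588). The zinc transporter SLC39A4 (ENSG00000147804) differed from NC by 0.07 and 0.06 on the log2 scale and did not pass (edgeR adjusted p 0.768 and 0.648).

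**Figure D1:**
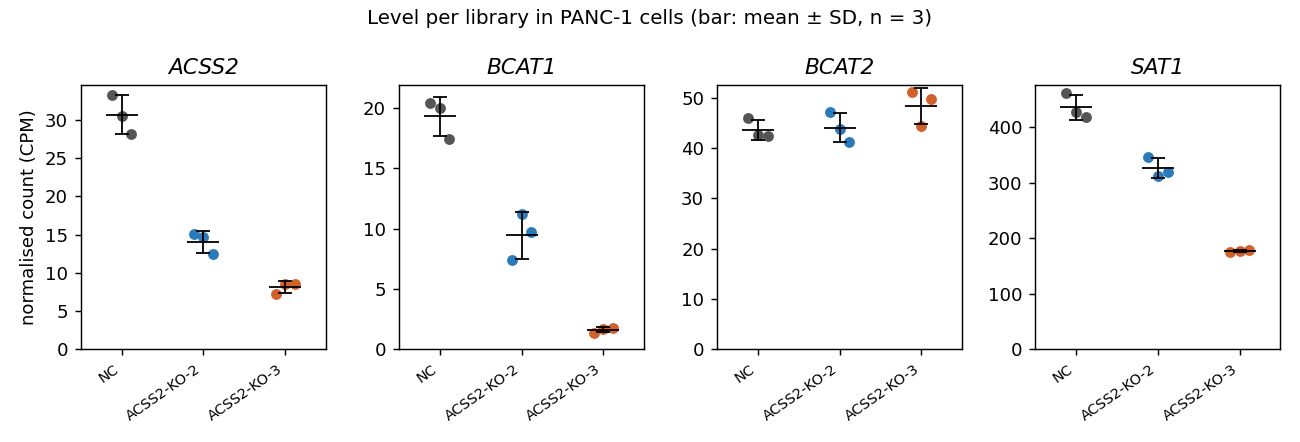
Normalised count in CPM (vertical axes, each from 0) of ACSS2, BCAT1, BCAT2 and SAT1 in NC, ACSS2-KO-2 and ACSS2-KO-3; points are libraries and lines are the mean and SD (n = 3). All knockout libraries lay below the NC libraries for ACSS2, BCAT1 and SAT1, while the BCAT2 means were 43.7, 44.1 and 48.5 CPM.

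In ACSS2-KO-2, transcripts that NC hardly contained appeared, and COL1A1, MMP2 and FOS were lower. CDKN2A, which encodes the cell-cycle inhibitors p16 and p14ARF, had 0 counts in the 3 NC libraries and 14.2 ± 0.593 CPM (SD, n = 3) in ACSS2-KO-2, at least 76.0-fold higher. IRS4, an adaptor of insulin receptor signalling, rose from 0 counts to 11.3 ± 0.355 CPM, at least 60.4-fold. COL1A1, the alpha chain of type I collagen, fell from 173 ± 9.66 to 94.9 ± 5.82 CPM (log2 fold change -0.86, edgeR adjusted p 1.39e-10), and the matrix protease MMP2 from 115 ± 1.44 to 61.7 ± 1.64 CPM (-0.90, 2.67e-11). FOS, the immediate early transcription factor, fell from 52.5 ± 4.55 to 26.1 ± 0.815 CPM (-1.01, 8.98e-10). The lists that hold such genes did not move as wholes. Of 29 mesenchymal and matrix genes 5 rose and 6 fell (5 and 8 adjusted over the list alone; camera adjusted p 0.615), and of 20 immediate early and heat shock genes 2 rose and 4 fell (2 and 5 adjusted over the list alone; camera adjusted p 0.975).

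Against NC, 1052 of 15811 genes (6.65%) passed in ACSS2-KO-2, 603 higher and 449 lower. Of the 308 that changed at least 2-fold, 274 were higher, and 228 of those averaged under 1 CPM in NC. 92 of the rises (15.3%) were of genes with at most 3 counts over the NC libraries, of which 50 had 0. Together these 92 made up 196 CPM in ACSS2-KO-2, 193 to 200 in its single libraries, and 10.9 CPM in ACSS2-KO-3. Among them were the homeobox genes HOXA10 (at least 20.2-fold), HOXD13 (at least 16.9-fold) and HOXA9 (at least 11.9-fold), which pattern the body axis and limbs. The others that the naming rule took as risen in both knockouts were UCHL1, a neuronal ubiquitin hydrolase (at least 26-fold), FBN2, a fibrillin of elastic fibres (21.9-fold), SLIT2, an axon guidance ligand (19.7-fold), LRP2, the endocytic receptor megalin (10.8-fold), and SLC16A10, an aromatic amino acid transporter (8.80-fold), each as a lower bound. UGT8, EYA4, PELI2 and SLC7A8, which the rule took for the difference between the knockouts, also belonged to the 92. PAX6, a transcription factor of islets, eye and brain, was 2.19 higher on the log2 scale (edgeR adjusted p 0.0069), a call lost without NC replicate 2 (1.80, 0.0612).

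CDKN2A lies on chromosome 9 (21967753 to 21995301) in a block that PANC-1 is known to lack, and the genes around it were read in the same way. MTAP (21802543 to 21937651), a methionine salvage enzyme next to CDKN2A, had 15 counts in NC, 138 in ACSS2-KO-2 and 26 in ACSS2-KO-3. It rose by 3.13 on the log2 scale in ACSS2-KO-2 (edgeR adjusted p 5.99e-07) and stood at 0.84 in ACSS2-KO-3 (0.127). CDKN2B had 0, 20 and 0 counts and CDKN2B-AS1 0, 5 and 0, too few to be tested. FOCAD, on one side of the block, had 2219, 2429 and 2537 counts, and DMRTA1, on the other, 98, 134 and 69. These genes were looked at after the CDKN2A value was seen.

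**Figure D2:**
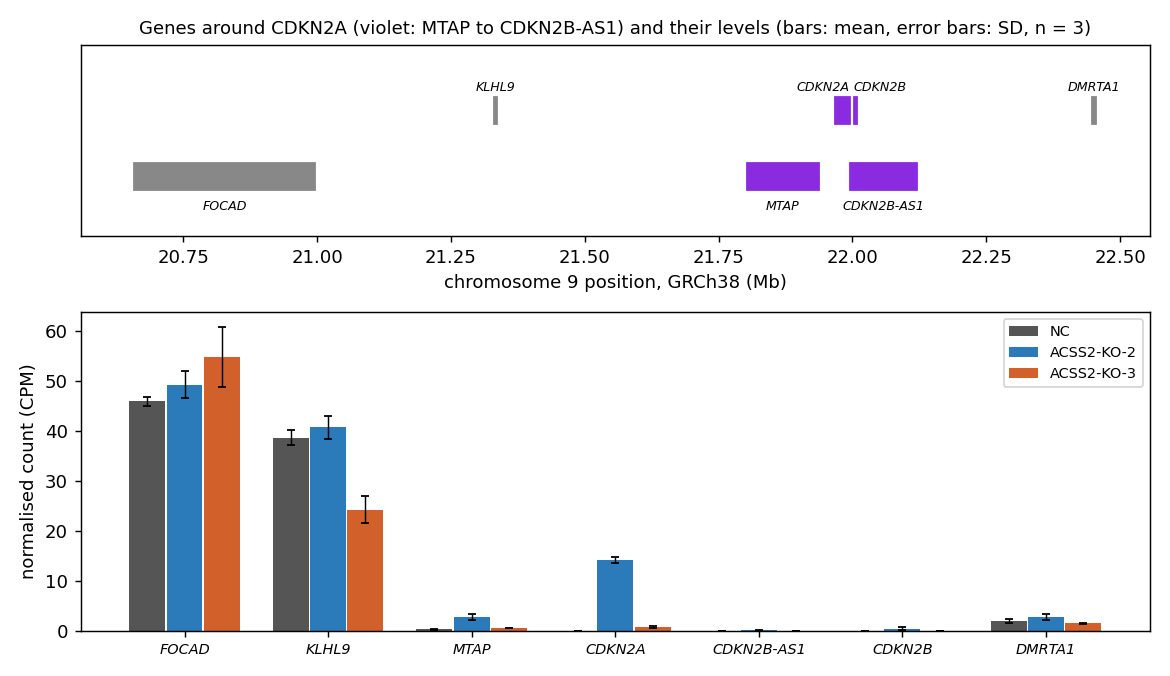
Position of genes around CDKN2A on chromosome 9 in GRCh38, in Mb (upper panel, violet for MTAP to CDKN2B-AS1), and their normalised counts in CPM (lower panel, bars for the mean and error bars for the SD, n = 3). CDKN2A reached 14.2 CPM and MTAP 2.78 CPM in ACSS2-KO-2, against 0 and 0.314 CPM in NC, while FOCAD was between 46.0 and 54.9 CPM in the group means.

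Among genes present in NC, TNFSF10, the death ligand TRAIL, fell from 4.42 ± 0.304 to 1.62 ± 0.532 CPM (log2 fold change -1.43, edgeR adjusted p 0.000113), and the cyclic AMP phosphodiesterase PDE4B from 7.62 ± 0.414 to 2.92 ± 0.295 CPM (-1.38, 2.3e-06). CCDC180, a protein of motile cilia, fell by 1.92 on the log2 scale (edgeR adjusted p 0.00222). SCD, which introduces the double bond of oleate, fell from 4161 ± 106 to 3329 ± 111 CPM (-0.32, 2.17e-05). DDIT4 (-0.46, edgeR adjusted p 7.16e-06) and NUPR1 (-0.55, 3.85e-07), both induced by stress, fell. BIRC3, an inhibitor of apoptosis under NF-kB control, rose by 0.42 (0.000135), the chaperone HSPA8 by 0.29 (0.00033) and the p53-induced nuclease AEN by 0.39 (0.000389). The lipid droplet protein HSD17B13 (-1.84, edgeR adjusted p 0.0117), the mucin MUC16 (-1.63, 0.0349), the lectin LGALS9 (-1.33, 0.043), the protease MMP28 (-1.32, 0.0496) and the ciliary gene PIFO (-1.20, 0.0312) averaged 1.04 to 1.63 CPM in NC and passed by small margins. None of these 5 passed with DESeq2, where their adjusted p values ran from 0.115 to 0.287. LGALS9 also failed with limma-voom (0.0558), no low-count filter (0.0538), the replicate block (0.0523) and the restriction to genes at 1 CPM or more in NC (0.0503), and MMP28 with RLE scaling (0.0516) and the last 3 of these (0.0685, 0.063 and 0.0561). All 5 calls were also lost on leaving out a single library. This held for HSD17B13 without NC replicate 2 (adjusted p 0.0524) or ACSS2-KO-2 replicate 2 (0.0824), for MUC16 without any NC library or ACSS2-KO-2 replicate 2 or 3 (0.0676 to 0.189), for LGALS9 without NC replicate 2 or 3 or any ACSS2-KO-2 library (0.0756 to 0.249), for MMP28 without any of the 9 libraries (0.0533 to 0.242) and for PIFO without NC replicate 1 or 3 or ACSS2-KO-2 replicate 2 or 3 (0.0781 to 0.198). RNU6-1 (-2.45) and RN7SL5P (-1.66), whose counts are uncertain because near-identical copies exist, were also lower in ACSS2-KO-2 with edgeR adjusted p values of 0.00202 and 0.00414, the latter lost with DESeq2 (0.271) and without NC replicate 2 (0.0585).

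By list, 5 of 24 passed camera in ACSS2-KO-2 and 0 passed with an estimated correlation, where only the cell cycle and hypoxia targets lists had an unadjusted p under 0.05, and 3 passed fry. Of 44 cell cycle genes 5 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p 7.11e-06, adjusted p = 0.449 with an estimated correlation), among them CDC25A, the phosphatase that activates cyclin-dependent kinases (0.60, edgeR adjusted p 3.48e-06). Of 20 ER chaperones 2 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p 0.0135, adjusted p = 0.477 with an estimated correlation). Both risers, chosen after their values were seen, were HSPA5 (0.19) and PDIA6 (0.21). Of 24 hypoxia targets 2 rose and 6 fell (3 and 10 adjusted over the list alone; camera adjusted p 0.0329 downward, adjusted p = 0.449 with an estimated correlation), with a median of -0.15 and a mean of 0.11. Both that rose, chosen after their values were seen, were EGLN3, with 3 counts in NC and 19.3 times that level here (95% counting interval 6.27 to 96.0), and CA12 (2.33, 0.348 CPM in NC), while BNIP3, a mitophagy receptor, fell by 0.47 (edgeR adjusted p 1.02e-06). EGLN3 was also among the 92 risen genes with at most 3 counts over NC. Of 22 glycolysis genes 0 rose and 4 fell (0 and 5 adjusted over the list alone; camera adjusted p 0.0159, adjusted p = 0.847 with an estimated correlation), among them the aldolase ALDOC (-0.61, edgeR adjusted p 0.00156). Of 13 mitochondrial genome transcripts 0 rose and 3 fell (0 and 4 adjusted over the list alone; camera adjusted p 0.0195, adjusted p = 0.889 with an estimated correlation), a list call lost with the offsets (camera adjusted p 0.258). With the offsets MAPK feedback genes (camera adjusted p 0.0294) and ribosomal protein genes (0.0367) passed, and 0 lists with an estimated correlation. Without them, MAPK feedback genes (3 rose and 1 fell, or 6 and 1 adjusted over the list alone; camera adjusted p 0.0511) and mesenchymal and matrix genes did not pass, and the latter had a median of 0.02 and a mean of 0.05 while camera and fry pointed downward. Without ACSS2-KO-2 replicate 2 the count of changed genes in this comparison was 666.

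In ACSS2-KO-3, a large part of the transcriptome differed from NC. The leucine transporter SLC7A5 rose from 546 ± 22.6 to 1261 ± 64.5 CPM (SD, n = 3; log2 fold change 1.21, edgeR adjusted p 4.07e-17, 0.98 with the offsets). CDC25A rose from 21.1 ± 0.876 to 55.4 ± 3.6 CPM (1.39, 6.43e-15; 1.24 with the offsets), and FOSL1, a transcription factor downstream of MAPK signalling, from 158 ± 4.01 to 336 ± 11.4 CPM (1.09, 7.57e-16; 0.93 with the offsets). COL1A1 fell to 64.1 ± 4.66 CPM (-1.43, 1.96e-16; -1.63 with the offsets), TNFSF10 to 0.605 ± 0.0814 CPM (-2.85, 1.14e-09; -2.27) and PDE4B to 2.61 ± 0.65 CPM (-1.55, 1.86e-08; -1.31). CENPF, a kinetochore protein of dividing cells, fell from 413 ± 20.4 to 84.8 ± 16.2 CPM (-2.28, 1.77e-17; -1.73 with the offsets).

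Of 15811 genes, 10006 (63.3%) passed in ACSS2-KO-3, 4938 higher and 5068 lower. At a fold of at least 2 there were 2215, of which 190 were higher and 2025 lower, or 1425 with the offsets, 262 higher and 1163 lower. The fold changes followed the GC content of the transcripts, with a rank correlation across 12903 protein-coding genes of 0.53 in ACSS2-KO-3 and -0.01 in ACSS2-KO-2. Of 2037 genes under 40% GC, 1666 (81.8%) were lower and 67 (3.29%) higher in ACSS2-KO-3, with a median of -0.84. Of 2077 genes at 60% GC or more, 236 (11.4%) were lower and 1131 (54.5%) higher, with a median of 0.28. With transcript length the rank correlation was -0.14 in ACSS2-KO-3 and 0.12 in ACSS2-KO-2. Transcripts of 8000 bases or more had a median of -0.24 in ACSS2-KO-3, and those of 1000 to 2000 bases 0.10. With the offsets the rank correlation with GC content was 0.01 and 9472 genes passed, 5540 higher and 3932 lower. Of the 10006 genes, 7225 passed in the same direction in both fits and 583 passed in opposite directions.

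**Figure D3:**
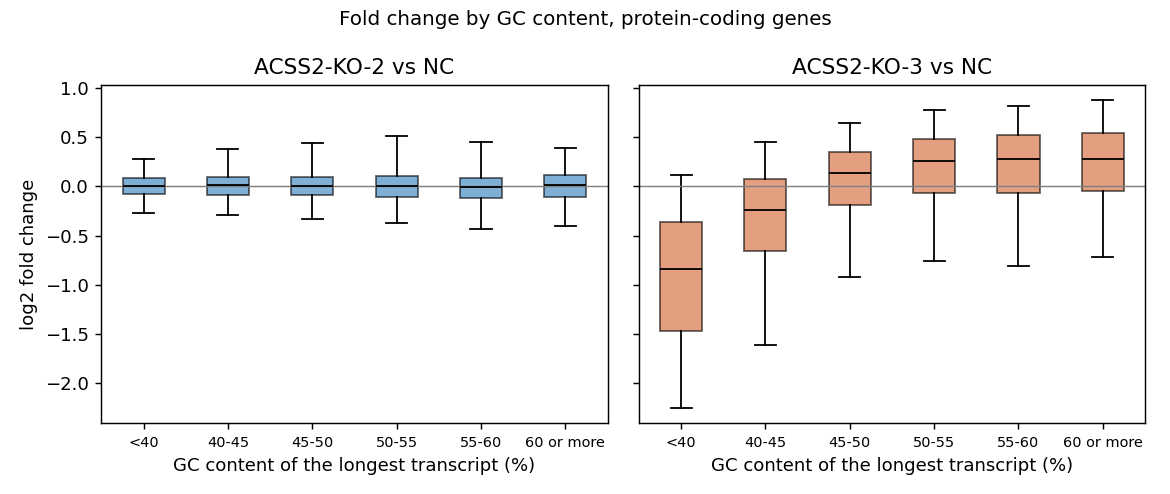
Log2 fold change against NC (vertical axes) of protein-coding genes by GC content of the longest transcript (horizontal axes, in %) in ACSS2-KO-2 and ACSS2-KO-3; boxes give the median and quartiles and whiskers the 5th and 95th percentiles. Medians in ACSS2-KO-3 ran from -0.84 under 40% GC to 0.28 at 60% or more, whereas those in ACSS2-KO-2 stayed between -0.01 and 0.01.

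Lipid genes moved both ways in ACSS2-KO-3. Of 26 fatty acid synthesis genes 9 rose and 12 fell (camera adjusted p 0.835; 10 and 9 with the offsets), of 23 cholesterol synthesis genes 8 rose and 9 fell (9 and 9 adjusted over the list alone; 0.889; 10 and 6 with the offsets), and of 19 fatty acid oxidation genes 8 rose and 3 fell (0.375; 11 and 4 with the offsets). SCD fell to 2804 ± 129 CPM (log2 fold change -0.57, edgeR adjusted p 3.31e-11; -0.61 with the offsets), as did ACSL4, which activates polyunsaturated fatty acids (-1.49, -0.65 with the offsets), the sterol carrier STARD4 (-1.72, -0.56) and IDI1 of the mevalonate pathway (-0.735, -0.29). ACADSB, which oxidises branched short-chain acyl-CoA in isoleucine breakdown, fell by 1.02 (-0.32 with the offsets), and so did ACADM, the medium-chain acyl-CoA dehydrogenase (-0.69, -0.23). PDK1, which inhibits pyruvate dehydrogenase, fell by 1.07 (-0.37), whereas citrate synthase CS rose by 0.55 (0.42) and ECI1, an isomerase of fatty acid oxidation, by 0.60 (0.44). SLC38A2, a glutamine and alanine transporter, fell by 0.89, or -0.11 with the offsets. RRM2B, a p53-induced ribonucleotide reductase subunit, fell by 1.09, but did not pass with the offsets (-0.15, edgeR adjusted p 0.0667). In polyamine metabolism, ODC1, which makes putrescine, rose by 0.78 (0.62 with the offsets) and SAT1 fell (-0.96 with the offsets). BIRC3 fell by 1.31, or -0.19 with the offsets, and IFIT1, an interferon-induced gene, fell by 1.16 (-0.82), while CSF1, the macrophage growth factor, rose by 0.86 (0.63) and the peptide transporter TAP1 by 0.77 (0.55). MMP2 (-0.56, -0.77 with the offsets), FOS (-0.85, -0.99), DDIT4 (-0.82, -0.98), NUPR1 (-0.52, -0.64), BNIP3 (-0.64, -0.80), ALDOC (-1.52, -1.68) and the tight junction gene CLDN7 (-0.51, -0.69) fell further with the offsets than without. Each change of a gene named in this paragraph, RRM2B with the offsets aside, passed the edgeR test in both fits.

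Several transcripts that were absent from NC were also higher in ACSS2-KO-3, at levels far under those of ACSS2-KO-2. IRS4 reached 0.724 ± 0.272 CPM (at least 3.88-fold), CDKN2A 0.707 ± 0.198 CPM (3.78-fold), SLIT2 0.537 ± 0.184 CPM (2.88-fold), HOXA9 0.436 CPM (2.34-fold), HOXA10 0.385 CPM (2.06-fold), FBN2 0.317 CPM (1.70-fold), HOXD13 0.239 CPM (1.28-fold) and UCHL1 0.209 CPM (1.12-fold), each as a lower bound. SLC16A10 and LRP2 passed the edgeR test, LRP2 not without ACSS2-KO-3 replicate 3 (adjusted p 0.107), but lay under the floor of the libraries, so no fold is given. MUC16 fell at least 5.87-fold to a level under the floor (edgeR adjusted p 3.61e-05). HSD17B13 (-2.22, -1.63 with the offsets), RN7SL5P (-2.03), CCDC180 (-1.76), LGALS9 (-1.53), RNU6-1 (-1.53), MMP28 (-1.37) and PIFO (-1.23) fell in ACSS2-KO-3 with edgeR adjusted p values from 5.61e-05 to 0.00565, except that MMP28 did not pass with DESeq2 (0.0532) and RNU6-1 did not without NC replicate 2 (0.0519).

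By list, 6 of 24 passed camera in ACSS2-KO-3, 0 with an estimated correlation (unadjusted p under 0.05 for the cell cycle and hypoxia targets lists) and 17 with fry. Of 44 cell cycle genes 33 rose and 9 fell, with a median of 0.60 (camera adjusted p 5.08e-06, adjusted p = 0.43 with an estimated correlation; 36 rose and 6 fell with the offsets). The other way moved CENPF, and also CENPE (-2.73, -1.62 with the offsets), TOP2A (-1.28, -0.60) and KIF11 (-1.22, -0.475), which act in mitosis and were singled out after their values were seen. Of 24 hypoxia targets 3 rose and 15 fell, with a median of -0.52 (camera adjusted p 0.0134, adjusted p = 0.43 with an estimated correlation; median -0.21 with the offsets), among them PLOD2, a collagen lysyl hydroxylase (-1.35, -0.23 with the offsets). Of 20 ER chaperones 12 rose and 3 fell (camera adjusted p 0.0454, adjusted p = 0.568 with an estimated correlation). HYOU1 rose by 0.77 (0.59 with the offsets) and HSP90B1, the endoplasmic reticulum form of HSP90, fell by 1.19 (-0.76). Of 37 cytosolic ribosomal protein genes 24 rose and 3 fell (24 and 4 adjusted over the list alone; camera adjusted p 0.00473, adjusted p = 0.639 with an estimated correlation), with RPL8 at 0.54 (0.42 with the offsets) and RPS15 at 0.52 (0.37). Of 29 lysosome and autophagy genes 16 rose and 4 fell (camera adjusted p 0.0134, adjusted p = 0.61 with an estimated correlation), with the autophagy receptor SQSTM1 at 0.77 (0.55 with the offsets) and the membrane protein LAMP1 at 0.565 (0.43). Of 22 glycolysis genes 16 rose and 3 fell (camera adjusted p 0.00799, adjusted p = 0.61 with an estimated correlation), with transketolase TKT at 0.61 (0.46 with the offsets). The lysosome and glycolysis calls were lost with the offsets (camera adjusted p 0.286 and 0.168). Mitochondrial genome transcripts passed only with them (11 rose, 0 fell, camera adjusted p 0.0149, adjusted p = 0.651 with an estimated correlation). Without them 5 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p 0.339). The list median was 0.11 without and 0.45 with the offsets. The offsets were fitted over all genes, but mitochondrial heavy-strand mRNAs did not share the GC slope of nuclear mRNAs (-0.0016 against 0.053). The offsets themselves may therefore have made this call. MT-ND1 was at 0.41 without and 0.46 with the offsets. Among 24 BCAA catabolism genes 6 rose and 12 fell (camera adjusted p 0.24), and among 16 amino acid transporters 10 rose and 4 fell (0.175, median 0.45, mean -0.06).

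**Figure D4:**
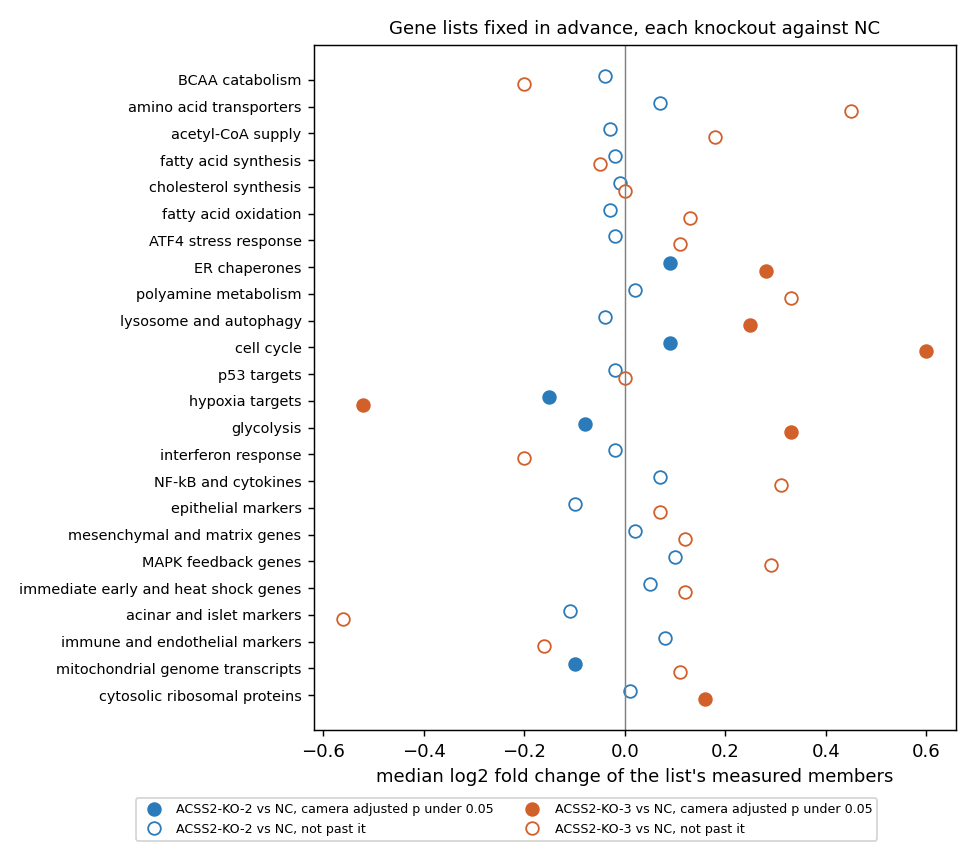
Median log2 fold change against NC (horizontal axis) of the measured members of 24 gene lists (vertical axis) in ACSS2-KO-2 and ACSS2-KO-3; filled points passed camera with the preset correlation. Cell cycle genes lay at 0.09 in ACSS2-KO-2 and 0.60 in ACSS2-KO-3 and hypoxia targets at -0.15 and -0.52, while glycolysis genes lay at -0.08 and 0.33; 0 lists passed with an estimated correlation.

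Both knockouts shared lower BCAT1, COL1A1, SAT1, SCD, FOS, PDE4B, DDIT4 and NUPR1 and higher CDC25A, AEN and HSPA8. As the mean of both knockouts against NC, COL1A1 fell by 1.15 on the log2 scale (edgeR adjusted p 7.57e-15). FOS (-0.93, 1.57e-11), PDE4B (-1.46, 4.63e-09) and SCD (-0.45, 6.67e-10) also fell. CDC25A rose by 1.00 (4.59e-12), AEN by 0.72 (2.85e-10) and HSPA8, a constitutive chaperone, by 0.56 (1.28e-10). EPHA2, a receptor tyrosine kinase, rose by 0.51 (3.02e-10). In this mean, 7884 genes passed, 3856 higher and 4028 lower, or 176 higher and 557 lower at a fold of at least 2. With the offsets 7497 genes passed, 4447 higher and 3050 lower. Of the 7884, 5685 passed in the same direction and 221 in the opposite one with the offsets. A gene can pass in this mean through 1 knockout alone. In the separate comparisons 1052 genes passed in ACSS2-KO-2 and 10006 in ACSS2-KO-3.

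Changed in the same direction in both separate comparisons were 566 genes, 287 higher and 279 lower (859 with the offsets, 442 higher and 417 lower), and 129 were changed in opposite directions, among them BIRC3. The 287 include 25 of the 92 genes with at most 3 counts over NC that rose in ACSS2-KO-2. For those 92, RNA of another cell line is a candidate explanation, so the 25 may not be a shared response. If the calls of each knockout fell independently, 188 higher and 144 lower genes would be shared. Both comparisons use the same NC libraries, which makes their fold changes correlate by itself. In 20 simulations of unchanged groups with shared controls the correlation was 0.481 to 0.516, and the observed value across genes was 0.345 (0.395 with the offsets), but the covariance was 0.172 against 0.0165 to 0.0178. That covariance takes in genes at 0 in NC with very large fitted values, such as CDKN2A (10.83 and 6.52). Their part in it was not measured, so the larger covariance does not by itself show a shared response. How many calls shared controls alone would make 2 changed groups share was not simulated. The share of genes with the same sign was 62.1% (64.9% with the offsets), against 66.0 to 67.0% in the simulations. The 3 NC libraries could not be divided between the comparisons, so part of the overlap may come from the shared controls. The count of shared genes was 345 without NC replicate 1, 338 without NC replicate 2, 310 without ACSS2-KO-2 replicate 2 and 358 without ACSS2-KO-2 replicate 3.

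A model that treats the 6 knockout libraries as 1 group, chosen after seeing the data, counts the spread between the knockouts as error and called 6 genes (2825 at an unadjusted p under 0.05). They were FOS (-0.93, edgeR adjusted p 0.0165), PDE4B (-1.46, 0.0165), EGR1 (-0.89, 0.0223), NUPR1 (-0.54, 0.0411), HSPA1B (0.68, 0.0406) and NPTX1 (2.30, 0.0165). FOS and EGR1 are immediate early transcription factors, HSPA1B is an inducible chaperone whose reads are shared with HSPA1A, and NPTX1 is a neuronal pentraxin. EGR1, HSPA1B and NPTX1 were named because the count was small, after their values were seen.

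Among the 24 lists, 5 passed camera for the mean of both knockouts, 0 with an estimated correlation (unadjusted p under 0.05 for the cell cycle and hypoxia targets lists) and 15 with fry. Of 44 cell cycle genes 32 rose and 7 fell (32 and 8 adjusted over the list alone; camera adjusted p 3.91e-07, adjusted p = 0.314 with an estimated correlation). Of 24 hypoxia targets 4 rose and 12 fell (4 and 13 adjusted over the list alone; camera adjusted p 0.0189, adjusted p = 0.314 with an estimated correlation). Of 37 cytosolic ribosomal protein genes 19 rose and 1 fell (camera adjusted p 0.0126, adjusted p = 0.763 with an estimated correlation), of 20 ER chaperones 10 rose and 3 fell (camera adjusted p 0.0267, adjusted p = 0.43 with an estimated correlation), and of 20 MAPK feedback genes 10 rose and 3 fell (camera adjusted p 0.0376, adjusted p = 0.43 with an estimated correlation). The MAPK call was lost without NC replicate 3 (camera adjusted p 0.0814) or ACSS2-KO-2 replicate 3 (0.0569) or ACSS2-KO-3 replicate 3 (0.0507). Without ACSS2-KO-3 replicate 2 the lysosome list passed (0.0437). A list can also pass in the mean through 1 knockout. Of the 37 ribosomal protein genes, 1 rose in ACSS2-KO-2 against NC (camera adjusted p 0.462) and 24 in ACSS2-KO-3 against NC.

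The remaining lists did not pass camera for the mean of both knockouts. In BCAA catabolism 5 of 24 genes rose and 8 fell (camera adjusted p 0.242), among the latter BCAT1 and ACADSB. ACADSB passed in the mean through ACSS2-KO-3, since in ACSS2-KO-2 it stood at 0.009 (edgeR adjusted p 0.971). Of 16 amino acid transporters 8 rose and 4 fell (0.0826), of 20 acetyl-CoA supply genes 7 rose and 2 fell (0.268), of 26 fatty acid synthesis genes 6 rose and 9 fell (7 and 10 adjusted over the list alone; 0.657), of 23 cholesterol synthesis genes 6 rose and 6 fell (8 and 6 adjusted over the list alone; 1) and of 19 fatty acid oxidation genes 6 rose and 4 fell (0.657). Of 32 ATF4 stress response genes 9 rose and 7 fell (0.769), of 15 polyamine genes 8 rose and 2 fell (9 and 2 adjusted over the list alone; 0.169), of 29 lysosome and autophagy genes 13 rose and 2 fell (0.0917), of 21 p53 targets 5 rose and 7 fell (0.866) and of 22 glycolysis genes 11 rose and 3 fell (0.111). Of 24 interferon response genes 5 rose and 9 fell (0.769), of 19 NF-kB and cytokine genes 7 rose and 4 fell (0.542), of 17 epithelial markers 4 rose and 5 fell (0.852), with ESRP2, an epithelial splicing regulator, at 0.39, and of 29 mesenchymal and matrix genes 11 rose and 10 fell (11 and 11 adjusted over the list alone; 0.877). Of 20 immediate early and heat shock genes 9 rose and 6 fell (0.515), of 6 acinar and islet markers 1 rose and 1 fell (0.548), of 3 immune and endothelial markers 0 rose and 0 fell by edgeR (0.852), and of 13 mitochondrial genome transcripts 1 rose and 1 fell (0.976). Among the islet markers the calls were PAX6 and the granin CHGB (-0.50, edgeR adjusted p 0.0225). PAX6 did not pass without NC replicate 2 (0.0699), and CHGB did not without NC replicate 2 (0.0649), NC replicate 3 (0.176) or ACSS2-KO-2 replicate 2 (0.0575), nor with DESeq2 (0.11). Signs differed in the cholesterol list (median -0.04, camera upward), fatty acid oxidation (median 0.04, mean -0.03), ATF4 (0.02 and -0.03), NF-kB (0.07 and -0.02), mesenchymal genes (median 0.06, fry downward) and mitochondrial transcripts (median -0.01, mean 0.01).

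The last comparison asks where the knockouts differed from each other. ATOH8, a basic helix-loop-helix factor, was at 24.3 ± 2.4 CPM in ACSS2-KO-3 and 7.79 ± 0.983 in ACSS2-KO-2 (SD, n = 3; log2 difference 1.64, edgeR adjusted p 3.26e-12), and the collagen COL26A1 at 13.0 ± 1.33 against 4.44 ± 0.0649 CPM (1.55, 2.87e-10). TMEM52B (1.89, 3.55e-05) and the dopamine receptor DRD2 (1.62, 0.00257) were also higher in ACSS2-KO-3, as was the pseudogene FTH1P11 (2.27, 0.000276), whose counts are uncertain. NC held DRD2 at 1.11 CPM, close to the 1.01 CPM of ACSS2-KO-3 and above the 0.325 CPM of ACSS2-KO-2. HOOK1, a linker of endosomes to microtubules, had 4.14 ± 0.152 CPM in ACSS2-KO-2 and 0 counts in ACSS2-KO-3, at least 21.3-fold lower. UGT8, which makes galactosylceramide, was at least 8.75-fold lower, the phosphatase EYA4 8.20-fold, the ubiquitin ligase PELI2 7.78-fold and the amino acid transporter SLC7A8 7.23-fold. In NC, HOOK1 had 13 counts, EYA4 0, and UGT8, PELI2 and SLC7A8 had 2 each, so that ACSS2-KO-2 held 40.6 times (10.9 to 341), 36.2 times (9.68 to 305) and 34.3 times (9.14 to 288) the NC level of these last genes.

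Between the knockouts 9756 genes differed, 4936 higher and 4820 lower in ACSS2-KO-3. At a fold of at least 2 there were 2178, 101 higher and 2077 lower. With the offsets 9022 genes differed, 5360 higher and 3662 lower, and 6834 of the 9756 kept their direction and call while 594 turned. 6 lists passed camera and 0 with an estimated correlation (unadjusted p under 0.05 for hypoxia targets), with 20 past fry. Higher in ACSS2-KO-3 were cell cycle genes (33 rose, 9 fell; camera adjusted p 6.02e-05, adjusted p = 0.57 with an estimated correlation), glycolysis (17 and 2; 0.000424, adjusted p = 0.57 with an estimated correlation) and lysosome and autophagy (17 and 4, or 20 and 4 adjusted over the list alone; 0.0049, adjusted p = 0.57 with an estimated correlation). So were ribosomal protein genes (25 and 3; camera adjusted p 0.00696, adjusted p = 0.573 with an estimated correlation) and mitochondrial genome transcripts (10 and 0, or 11 and 0 adjusted over the list alone; 0.0411, adjusted p = 0.573 with an estimated correlation). Hypoxia targets were lower (4 rose, 17 fell; camera adjusted p 0.0149, adjusted p = 0.484 with an estimated correlation). With the offsets the lysosome (0.135), ribosomal protein (0.0926) and hypoxia (0.0507) calls were lost.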

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

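The counts of other splits of the libraries were planned, and all other tests of technical or biological explanations in this part were chosen only after the result they measure had been seen. What drew attention here was that both knockouts, set against the same NC libraries, differed from each other by the edgeR test of the difference itself. Groups of 3 are too small for a test of single outlying libraries.

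Transcripts of low GC content were lower in ACSS2-KO-3, with a median log2 fold change of -0.84 over 2037 genes under 40% GC, and every ACSS2-KO-3 library carried the trend. The trend as fitted is not the whole account of the calls, since 9472 genes passed with it entered as offsets. The offsets use the longest transcript of each gene, so a GC-related bias in the remaining calls is not excluded. A poorer recovery of low-GC reads in the ACSS2-KO-3 libraries would give the 12 mitochondrial heavy-strand mRNAs, which are transcribed together, the slope of nuclear mRNAs of the same GC range (0.053 per percent GC, 95% interval 0.032 to 0.076). Their slope was -0.0016 (-0.045 to 0.047), and the difference of -0.055 (-0.11 to -0.0039) excluded 0 narrowly. That interval treats genes as independent, although the 12 mRNAs are transcribed together and were measured in the same libraries. It may be too narrow, so the slopes weigh at most weakly against poorer recovery of reads. An effect in proportion to the fall of ACSS2 RNA predicted -0.49 in ACSS2-KO-2, where the median was 0.01. This argues only against an effect that follows ACSS2 RNA in proportion. RNA does not show how much ACSS2 function each knockout lost. An effect particular to the ACSS2-KO-3 cells was not tested, and because the trend follows 1 group, the preparation of its libraries and the biology of its cells cannot be told apart.

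Genes with at most 3 counts over NC were higher in ACSS2-KO-2, 92 in number, and RNA of another cell line in the ACSS2-KO-2 libraries is a candidate explanation. PANC-1 is known to carry a homozygous deletion that includes CDKN2A, and both genes of that block with enough counts to be tested, CDKN2A and MTAP (2 of 4), were higher, while CDKN2B went from 0 to 20 counts and CDKN2B-AS1 from 0 to 5; the criterion was set after these values were seen. For HEK293 cells, 8 of 10 listed genes were higher, but 8 of the 10 had been seen when the list was written, and of the other two LIN28B was higher (0.54) and ZIC2 was not called (0.24, edgeR adjusted p 0.0758), so HEK293 cannot be told apart from another source. Activation in proportion to the loss of ACSS2 RNA would leave ACSS2-KO-3, with less of that RNA, at the ACSS2-KO-2 level or above it. The median ratio of ACSS2-KO-3 to ACSS2-KO-2 was 0.046 (0.036 to 0.053) and 0 of the 92 genes reached 1. The 92 were picked as higher in ACSS2-KO-2, which by itself favours ratios under 1. The ratio therefore covers only these genes, and only activation that follows ACSS2 RNA, which does not show the function lost. A response of PANC-1 cells that lack the block is argued against for the genes of the block, since CDKN2A had at least 210 counts in each ACSS2-KO-2 library against 0 in NC, and was not tested for the other genes. A mixed library and cells of another origin may each remain open, and the smaller amounts in ACSS2-KO-3 (25 of the 92 called higher by edgeR) were not explained by any test here.

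BCAT1 was lower in both knockouts. The GC trend as the sole cause is argued against by the value with the offsets, -2.74 in ACSS2-KO-3, and 1 of 431 genes matched for GC content and length lay as low (matched median -1). Dilution of ACSS2-KO-2 by RNA of other cells would lower many NC genes alike, but 33 of 14142 genes (0.233%) fell as far as BCAT1. A lower BCAT1 transcript level in these knockout cells may be biological, as a hypothesis that was found and examined on the same data. Whether it follows from ACSS2 or from the selection of these cells was not tested, and the preparation of the libraries remains confounded with the groups.

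For each pair of groups, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. Fitted on the libraries of the pair alone, the real counts by edgeR were 1371 for ACSS2-KO-2 against NC, 9706 for ACSS2-KO-3 against NC and 9447 for ACSS2-KO-3 against ACSS2-KO-2, and the highest other split gave 0 in each case. At an unadjusted p under 0.05 the real splits gave 3282, 10147 and 9959 genes and the highest other splits 1032, 116 and 111. With the 6 knockout libraries as 1 group, 3 of 84 splits gave as many as the real 6 genes. The highest other split gave 9972, which sets ACSS2-KO-3 against the rest and points to a structure of the samples, and that of ACSS2-KO-2 against the rest gave 255. Splits that mix the groups hold the ACSS2-KO-3 differences in their error, so the number of splits does not show whether chance can be excluded for that count. For the gene lists, 17 of 84 splits gave as many as the real 5, with 6 in the highest other split, so chance cannot be excluded for the number of lists.

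Between the knockouts 9756 genes differed, and of the 80 genes named by the rule 67 did, 40 lower and 27 higher in ACSS2-KO-3. All values that follow are log2 differences of ACSS2-KO-3 minus ACSS2-KO-2 with edgeR, unless another unit is given. The genes of the series title and the fixed set differed by -0.80 (ACSS2), -2.55 (BCAT1, -1.67 with the offsets), 0.27 (ETV4, 0.03 with the offsets and then not called) and -0.88 (SAT1). Transcripts at 0 in ACSS2-KO-3 measured 4.14 CPM (HOOK1), 1.70 CPM (UGT8), 1.60 CPM (EYA4), 1.515 CPM (PELI2) and 1.41 CPM (SLC7A8) in ACSS2-KO-2. Of those absent from NC, the differences were -3.93 (IRS4), -4.30 (CDKN2A), -2.76 (SLIT2), -2.34 (HOXA9), -3.26 (HOXA10), -3.63 (FBN2), -3.69 (HOXD13) and -4.45 (UCHL1), and TNFSF10 differed by -1.43 (-0.87 with the offsets). SLC16A10 (fitted value -3.19) and LRP2 (fitted value -3.88) lay under the floor in ACSS2-KO-3, so that the fitted values are no bounds, and were at least 8.44-fold and 10.4-fold lower there than in ACSS2-KO-2.

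In amino acid and acetyl-CoA metabolism the differences were -1.03 (ACADSB, -0.31 with the offsets), 1.23 (SLC7A5), -0.82 (SLC38A2, -0.04 and not called with the offsets), -0.73 (PDK1, 0.02 with the offsets) and 0.51 (CS). In lipid metabolism they were -1.49 (ACSL4, -0.64 with the offsets), -0.25 (SCD), -1.61 (STARD4, -0.475 with the offsets), -0.65 (IDI1), -0.56 (ACADM, -0.12 and not called with the offsets) and 0.41 (ECI1). Stress, polyamine and lysosome genes differed by -0.37 (DDIT4), -1.23 (HSP90B1), 0.61 (HYOU1), 0.63 (ODC1), 0.59 (SQSTM1), 0.53 (LAMP1), 0.54 (HSPA8), and p53 targets by 0.66 (AEN) and -0.96 (RRM2B, -0.02 with the offsets). Cell cycle genes differed by -2.38 (CENPF, -1.79 with the offsets) and 0.79 (CDC25A), hypoxia and sugar metabolism genes by -1.25 (PLOD2, -0.15 with the offsets), -0.16 (BNIP3), -0.91 (ALDOC) and 0.56 (TKT), and interferon and NF-kB genes by -0.86 (IFIT1), 0.59 (TAP1), 0.58 (CSF1) and -1.73 (BIRC3, -0.63 with the offsets). The BNIP3 difference did not pass with DESeq2 (adjusted p 0.057), with no low-count filter (0.0529) or without ACSS2-KO-2 replicate 1 (0.0537) or 3 (0.0626) or ACSS2-KO-3 replicate 1 (0.0677) or 3 (0.0692).

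Epithelial, matrix and MAPK genes differed by -0.25 (CLDN7), 0.39 (ESRP2), -0.57 (COL1A1), 0.33 (MMP2), 0.95 (FOSL1) and 0.64 (EPHA2). Islet markers differed by -1.15 (PAX6) and -0.76 (CHGB), mitochondrial transcripts by 0.49 (MT-ND1) and 0.13 (MT-CO3), and ribosomal protein genes by 0.40 (RPL8) and 0.37 (RPS15). PAX6 did not pass with DESeq2 (adjusted p 0.164), with no low-count filter (0.0512), with the offsets (0.212) or without ACSS2-KO-2 replicate 1 (0.091) or 3 (0.0842) or ACSS2-KO-3 replicate 1 (0.0569) or 2 (0.151). MT-CO3 did not pass with upper quartile scaling (0.0818), a mean of at least 1 CPM (0.0662) or only the groups compared (0.0545), or without ACSS2-KO-2 replicate 3 (0.0797) or ACSS2-KO-3 replicate 3 (0.155). The highest differences were 2.27 (FTH1P11), 1.89 (TMEM52B), 1.64 (ATOH8), 1.62 (DRD2) and 1.55 (COL26A1). The medians of the 6 lists past camera were 0.27 (lysosome and autophagy), 0.48 (cell cycle), -0.38 (hypoxia targets), 0.42 (glycolysis), 0.19 (mitochondrial genome transcripts) and 0.17 (cytosolic ribosomal proteins), and 0 of these passed with an estimated correlation, where hypoxia targets alone had an unadjusted p under 0.05.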

How the results depend on the processing

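Chosen only after the data were seen were the offsets for GC content and length, the restriction to genes at 1 CPM or more in NC and the model of 6 knockout libraries as 1 group, and the other alternatives were planned. Main counts were 1052 (ACSS2-KO-2 against NC), 10006 (ACSS2-KO-3 against NC), 7884 (mean of both), 9756 (ACSS2-KO-3 against ACSS2-KO-2), 566 (shared) and 5 lists. RLE and upper quartile scaling, DESeq2, limma-voom, both other low-count filters, the pairs of groups alone, the replicate block and the restriction to NC genes left each gene count computed within 1.5 times its main value (the mean was not computed for the pairs alone), with 729 to 1371, 9116 to 10041, 6870 to 7953, 8905 to 9864 and 412 to 731. A fold of at least 2 gave 308, 2215, 733, 2178 and 68, because fewer genes reach it. With the 6 knockout libraries as 1 group, 6 genes passed in place of 7884, since the spread between the knockouts then counts as error. The offsets gave 1461, 9472, 7497 and 9022 genes and 859 shared ones, and the cause of the last was not tested. With an estimated correlation 0 lists passed camera (unadjusted p under 0.05 for 2), and 15 passed fry, which does not compare a list with other genes. RLE scaling, the block and the offsets gave 5 lists, and lists were not run under the other settings above.

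Leaving out 1 library at a time gave 666 to 1295, 9296 to 10070, 6790 to 8014, 9109 to 9890 and 310 to 661 genes and 4 to 6 lists. The count for ACSS2-KO-2 fell to 666 without its replicate 2, and shared genes fell to 345 and 338 without NC replicate 1 and 2 and to 310 and 358 without ACSS2-KO-2 replicate 2 and 3; with fewer libraries each test has less power. With the replicate number as a block the counts were 1113, 10022, 7918, 9745 and 608, with 5 lists, although the numbers do not pair, and LGALS9 (-1.32, adjusted p 0.0523) and MMP28 (-1.32, 0.063) in ACSS2-KO-2 no longer passed.

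Of the named genes' values on leaving out a library, 2308 kept their direction and side of the threshold, 76 lost and 4 gained a call and 6 turned. With the offsets 250 kept both, 8 lost and 1 gained a call and 7 turned, and with DESeq2 250, 15, 0 and 1. BCAT2 in ACSS2-KO-2 ran from -0.04 (without ACSS2-KO-2 replicate 1) over 0.00 (without NC replicate 3) to 0.06. With the offsets it was -0.07 in ACSS2-KO-3, -0.02 in the mean and -0.10 between knockouts. SLC39A4 in ACSS2-KO-3 ran from -0.04 to 0.13 on leaving out a library and was -0.14 with the offsets, and -0.02 in the mean. Between knockouts SLC39A4 ran from -0.11 to 0.05 on leaving out a library, was 0.00 with DESeq2 and gained a call with the offsets (-0.22, adjusted p 0.0455). With the offsets BIRC3 was 0.12 in the mean (main -0.44) and PDK1 0.02 between knockouts (main -0.73). The offsets remove the GC trend by construction, and the cause of the other reversals, all of values near 0, was not tested. Scaling moved the median of all genes by less than 0.1. At this depth a gene under about 0.2 CPM in a library cannot be told from absent. Alternatives for FPKM values were not run.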

Other observations

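All tests in this part were chosen only after the values that prompted them had been seen. Genes of ribosome assembly in the nucleolus were higher in ACSS2-KO-3 than in NC. CCDC86 rose by 1.29 on the log2 scale, GRWD1 by 1.15, URB2 by 1.10, the helicase DHX37 by 1.08, BOP1, which processes the large subunit RNA, by 1.06, RRP12 by 0.94 and POLR1A, the catalytic subunit of RNA polymerase I, by 0.93. NOP58, a core protein of box C/D small nucleolar RNPs, fell by 1.00, or -0.54 with the offsets. These names were chosen after their values were seen.

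The inhibitors of differentiation ID1, ID2 and ID3, known targets of BMP signalling, were also higher in ACSS2-KO-3, by 1.12 (174 to 378 CPM), 1.82 and 1.36, beside ATOH8 (1.68). They too were chosen after their values were seen.

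Ribosome biogenesis factors in ACSS2-KO-3 were tested over the 24 list members whose values had not been seen when the list was written. Of these, 19 rose and 1 fell with the offsets (median 0.48, camera p 0.0138 with an estimated correlation). The list was prompted by genes seen in the same libraries, so its unseen members are not independent evidence. Over all 28 members the p was 0.0151, with 23 risen and 1 fallen. In ACSS2-KO-2, 5 of the 24 rose and 0 fell by edgeR with the offsets (median 0.10, camera p 0.024 with an estimated correlation). Each p is for a single list and was not adjusted over the lists fixed in advance. A rise of BMP and SMAD1/5 target genes as a set was not borne out over the 6 unseen members of 10, of which 1 rose and 1 fell (median 0.01, camera p 0.936 with an estimated correlation). In ACSS2-KO-2, 3 of the same 6 rose and 1 fell (median 1.22, camera p 0.0292 with an estimated correlation). The risers were HEY1 (1.78 CPM in NC, 12.3 in ACSS2-KO-2 and 2.01 in ACSS2-KO-3), BAMBI (0.102, 0.852 and 0.281 CPM) and ID4 (0.256, 1.30 and 0.24 CPM). Each was highest in ACSS2-KO-2, but none was among the 92 genes with at most 3 counts over NC. Whether their rise reflects BMP signalling or RNA of other cells was not tested.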
